A study of Mus musculus with 25 samples.

How the data were processed

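Poly(A) RNA from hypothalamus of 25 C57BL/6J mice was sequenced with a stranded mRNA library kit, per the labels' protocols. The labels give 8 groups by maternal diet, postnatal diet and sex, and 4 comparisons of maternal diet within a sex and postnatal diet. The labels do not say whether the samples of a group came from separate litters, so the p-values measure the spread between these samples.

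The submitters' processing notes name DESeq, with no version, and the genome build mm10, per the labels. The aligner, the counting tool and the gene annotation are not given in the sources used here. Of 12 deposited files, 4 tables of the authors' own comparisons were used. The mean over libraries is a normalized count, a signal that is never negative, per the file headers of the authors' tables. The fold change and its standard error are on the log2 scale, per the file headers of the deposited tables. The Wald statistic, a score with no fixed range, equalled the fold change divided by its standard error, to rounding, in the deposited tables. The p-value and the adjusted p-value are those the authors deposited. Genes with a mean normalized count under 10 carry the status Low in the authors' tables and have no adjusted p. In the table of RD-weaned males a further 1554 genes, and in that of RD-weaned females 342 genes, have the status OK and no adjusted p in the deposited tables.

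The other 8 deposited files hold counts and regularized log values in 48 columns of single libraries, which were not used. Their names are running numbers that match no label, so no column could be given a sample or a group. For the comparison of RD-weaned males, each such file has 6 library columns where the labels list 7 samples. The planned count test, its alternatives of normalization, tool and joint fit, leaving out libraries, blocks of replicate numbers, other splits of the samples, the check of sex-linked genes in each library, and the 4 comparisons of postnatal diet all need mapped libraries and were not run. The tests below replace them. Depth per sample is likewise not given here, and no error of a single sample can be stated.

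Which group stands in the numerator of a fold change is not stated in the tables. The labels call the RD-dam groups control and the HCD-dam groups comparison for the HCD-weaned offspring, and positive was read as higher in the HCD-dam group. The labels give no such word for the RD-weaned offspring, where the groups were read in the same order. If that reading is wrong for a table, all signs of that table turn together. The fold changes appear to be shrunken toward 0 by the authors' method: for RD-weaned females the median absolute log2 fold change was 0.05 in genes with a mean normalized count under 10 and 0.15 in genes with a mean of 100 or more in the deposited table, and the standard error did not exceed 0.30 in that table.

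A gene was called at an adjusted p under 0.05 in the authors' deposited table. Gene lists, 19 of pathways and 14 of cell types or neighbouring tissues, were fixed before the data were examined, and 543 of their 560 symbols occur in the tables. The 13 mitochondrially encoded symbols do not occur there, and lists with fewer than 3 tested members were not tested. Lists were tested with camera on the Wald statistics (cameraPR in limma 3.58.1, R 4.3.3) with a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over the lists of a comparison. A correlation cannot be estimated without mapped libraries, so preset values of 0.05 and 0.10 were tried in its place. Genes of a list were also adjusted over the list alone. Further alternatives were an adjusted p under 0.10, no filter on low counts, adjustment over genes with a mean of at least 10 or 100, the statistic divided by its robust spread, fold changes centred on their median, ranks or fold changes in camera, and removal of the trend below. The difference between 2 comparisons was divided by the root of the sum of the squared standard errors and referred to the normal distribution, with Benjamini-Hochberg adjustment over genes with an adjusted p in both tables. Since the fold changes look shrunken, this test of a difference can be conservative. The largest standard error was 0.33 in HCD-weaned males, 0.45 in HCD-weaned females, 0.45 in RD-weaned males and 0.30 in RD-weaned females. The degree of shrinkage may therefore differ between comparisons, which was not tested. If it does, equal effects can also appear to differ. The same 33 lists were tested on the differences. For the 3 differences that subtract a table of RD-weaned offspring, genes and lists were also tested with the sign of that table turned. Lists of imprinted genes (38 symbols), of RNAs without a poly(A) tail (34 symbols) and of further telencephalic genes (12 symbols) were written after the data had been examined. They serve the closing tests, and the second is also given beside the genes of HCD-weaned females.

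Named genes followed a rule fixed before the data were examined: the 8 called genes with the largest positive and the 8 with the largest negative fold change at a log2 CPM of at least 1, the 3 members of smallest p in each list that passed or held called genes, 4 feeding peptides, and up to 4 genes for each difference. The log2 CPM was taken from the share of the mean normalized counts. The part of the rule that asks for groups without overlap could not be applied. Genes with predicted names were counted and not named. Not every gene that the rule names is described singly, and 1 gene is not reported here. Genes named after their values were seen are marked as such or are shared or compared between tables.

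Transcript length and GC content came from the longest transcript in GENCODE M21 on GRCm38, the assembly behind mm10, for 23376 of 24421 symbols. Their trend in the Wald statistic was removed with splines of 5 knots (scikit-learn 1.9.0). Length and GC accounted for 32.9% of the variance of the Wald statistic in HCD-weaned males, 20.9% in HCD-weaned females, 5.12% in RD-weaned males and 5.90% in RD-weaned females. Gene positions are also from GENCODE M21. Random lists were drawn 10000 times, each member replaced by 1 of its 50 nearest genes. Computations used Python 3.11.15, scipy 1.17.1 and pandas 2.3.3.

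The steps were tested on simulated data that kept the real standard errors, with 200 changed genes per table. Of genes with a log2 change of 2, the call recovered 100% in HCD-weaned males (15384 genes), 98% in HCD-weaned females (15043 genes), 94% in RD-weaned males (12920 genes) and 100% in RD-weaned females (15028 genes). Of genes with a log2 change of 1, it recovered 59%, 35%, 19% and 71% in the same order. A list shifted by design was called in 4 of 4 simulated tables, and 0 of 119 tests of other lists passed. The simulated genes varied independently, so the latter count says nothing about false list calls among correlated genes. The test of a difference between the sexes on HCD recovered 16.5% of simulated differences of 1 and 87.7% of differences of 2 among 14947 genes. It recovered 14.4% and 81.5% between sexes on RD (12636 genes), 7.69% and 71.8% between diets in males (12910 genes) and 20.1% and 88.3% between diets in females (14603 genes). The simulated fold changes were not shrunken, so these rates can overstate what the test recovers from the deposited values.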

Results

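Gene expression was measured by stranded poly(A) RNA sequencing in the hypothalamus, the brain region that controls feeding, energy use and hormone release, of 3-month-old C57BL/6J mice. Dams received either a hypercaloric diet (HCD, 52% fat and high in sucrose) or regular chow (RD) from 1 month before mating until the end of lactation, and their offspring were weaned onto either diet. The 25 samples fall into 8 groups of maternal diet, postnatal diet and sex, with 4 samples of RD-weaned males of RD dams and 3 samples in each of the other 7 groups. Each of the 4 comparisons asks how the hypothalamic transcriptome of offspring of HCD dams differs from that of offspring of RD dams, within 1 sex and 1 postnatal diet. The values are those of the authors' 4 deposited comparison tables, since the columns of single libraries carry running numbers that no label ties to a sample. Depth per sample is therefore not given here, and the mean normalized counts in the authors' deposited tables sum to between 15402649 and 26951335 per table. A positive fold change is read as higher in offspring of HCD dams. For the HCD-weaned offspring that reading follows the labels, which call the RD-dam group the control, and for the RD-weaned offspring it rests on the order of the groups alone.

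In males weaned onto HCD, neuropeptide genes of the hypothalamus had the largest negative fold changes. Oxt, the precursor of oxytocin, had a log2 fold change of -2.27 with a standard error of 0.31 in the authors' deposited table (adjusted p = 7.05e-09), a 4.82-fold difference. It lies on chromosome 2 from 130576173 to 130577054 in GRCm38. The mean log2 CPM of Oxt was 4.07 here, -0.14 in RD-weaned males, 5.03 in HCD-weaned females and 5.67 in RD-weaned females. That of Pmch varied less, from 6.86 to 8.22, as did that of Hcrt, from 3.95 to 5.79. Whether the spread of Oxt reflects diet, sex or the dissection was not tested. Pmch, which encodes melanin-concentrating hormone, stood at -1.93 ± 0.30 (SE) in the authors' deposited table (adjusted p = 1.23e-06) and Hcrt, which encodes the orexins, at -1.73 ± 0.32 (SE; adjusted p = 0.000519). Pmch lies on chromosome 10 from 88091072 to 88092375 and Hcrt on chromosome 11 from 100761069 to 100762931. The calcitonin receptor gene Calcr (-1.61 ± 0.33, SE; adjusted p = 0.00191) and the insulin receptor substrate gene Irs4 (-1.32 ± 0.31, SE; adjusted p = 0.0185) were also negative in the authors' deposited table. So was the synaptic vesicle gene Sv2c (-1.30 ± 0.32, SE; adjusted p = 0.0355 in the authors' deposited table). Positive values past the threshold in the authors' deposited table included Mif, a cytokine gene (1.14 ± 0.26, SE), the nicotinic receptor subunit gene Chrnb4 (1.32 ± 0.32, SE), the ribosomal protein gene Rps29 (1.08 ± 0.26, SE) and the glutathione transferase gene Gstp1 (1.06 ± 0.25, SE). In total 25 of 15384 genes tested had an adjusted p under 0.05 in the authors' deposited table, 7 positive and 18 negative.

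Among the gene lists, transcription factors that mark hypothalamic neurons were the most negative in these males, with 9 of 10 measured members below 0 and a median log2 fold change of -0.76 (camera adjusted p = 2.32e-10). Of these 10, 2 passed over all genes and 8 when adjusted over the list alone. The 2 were Fezf1 (-1.55 ± 0.32, SE) and Sim1 (-1.37 ± 0.32, SE), and Otp stood at -1.22 ± 0.32 (SE) with an adjusted p of 0.0726 in the authors' deposited table. Their expression was low, with a log2 CPM of -0.18, -0.02 and -0.32 in that order. Feeding and neuroendocrine peptides and receptors had 19 of 27 negative members (median -0.27, camera adjusted p = 2.29e-05). The 3 called members were Oxt, Pmch and Hcrt, and 9 passed adjusted over the list alone. Of the feeding peptides of the arcuate nucleus, none passed in the authors' deposited table: Pomc stood at -0.52 ± 0.33 (SE), Agrp at -0.09 ± 0.29, Npy at 0.36 ± 0.26 and Cartpt at 1.13 ± 0.32, the last with an adjusted p of 0.135. The log2 CPM of Agrp was low in every comparison, from -3.32 in RD-weaned males to -0.75 in RD-weaned females. Markers of other tissues moved with these groups. All 10 striatum markers were negative (median -0.63, camera adjusted p = 2.19e-06), with 0 called over all genes and 2 adjusted over the list alone. Of 12 markers of meningeal fibroblasts and collagen, 11 were negative (median -0.56, camera adjusted p = 1.43e-07), with 1 called over all genes and 5 adjusted over the list alone. Cortex and hippocampus markers had a median of -0.03 (camera adjusted p = 0.927). Ogn, a small proteoglycan gene of the meninges, was the called member of the meningeal list in the authors' deposited table (-1.20 ± 0.28, SE; adjusted p = 0.0185).

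Nuclear-encoded genes of oxidative phosphorylation were positive in 25 of 26 measured members in the HCD-weaned males (median 0.42, camera adjusted p = 2.98e-09), with 0 members called over all genes or adjusted over the list alone. Ndufs8, a subunit gene of complex I, stood at 0.79 ± 0.27 (SE) and Cox5a, a subunit gene of cytochrome c oxidase, at 0.75 ± 0.28 (SE) in the authors' deposited table, both with an adjusted p above the threshold (0.382 and 0.456). Cytosolic ribosomal protein genes were positive in 34 of 37 members (median 0.33, camera adjusted p = 1.28e-08), with Rps29 called over all genes and 3 members adjusted over the list alone. Genes for DNA methylation and chromatin enzymes had a median of -0.31 (camera adjusted p = 0.00109), with 0 members called over all genes or adjusted over the list alone. Kmt2a, a histone methyltransferase gene, stood at -0.91 ± 0.29 (SE; adjusted p = 0.266) in the authors' deposited table. Heat shock proteins (median 0.22), leptin, insulin and ghrelin signalling (median -0.26), synapse and fast transmission (median -0.20) and the renin-angiotensin list (median -0.15) passed with camera adjusted p between 0.0137 and 0.0312. These 4 lists held 0 members called over all genes. Adjusted over the list alone, 2 synapse members and 1 renin-angiotensin member passed. With a preset correlation of 0.05 between genes the calls of these 4 lists were lost (adjusted p between 0.0916 and 0.131), and that of chromatin enzymes was lost at 0.10 (adjusted p = 0.19). By ranks the renin-angiotensin list did not pass (adjusted p = 0.053). The Wald statistic fell with transcript length across genes in this table (Spearman rho = -0.545, across genes, which are not independent). With that trend and that of GC content removed, chromatin enzymes (adjusted p = 0.171), leptin signalling (0.451), synapse (0.834) and heat shock proteins (0.0627) no longer passed. The same removal gave 18 called genes, 4 positive and 14 negative, of which 13 were among the 25. Dividing the Wald statistic by its robust spread left 3 called genes, 0 positive and 3 negative.

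In females weaned onto HCD, the metallothionein gene Mt1 and genes of oxidative phosphorylation were positive. Mt1, a metal-binding metallothionein gene on chromosome 8 from 94179082 to 94180327, had a log2 fold change of 1.74 ± 0.21 (SE) in the authors' deposited table (adjusted p = 3.44e-12), a 3.33-fold difference. In HCD-weaned males Mt1 was also positive but did not pass in the authors' deposited table (1.00 ± 0.27, SE; adjusted p = 0.114). The related gene Mt2, chosen after its values were seen, stood at 1.29 ± 0.18 (SE; adjusted p = 2.79e-09) in HCD-weaned females in the authors' deposited table. Mif (1.45 ± 0.22, SE) and the cholecystokinin gene Cck (1.44 ± 0.28, SE) were also positive in these females in the authors' deposited table. The long noncoding RNA gene Snhg8 had the largest positive value among the named genes in the authors' deposited table (1.85 ± 0.37, SE; adjusted p = 0.000615). The largest negative values in the authors' deposited table belonged to Rpph1 (-2.12 ± 0.45, SE) and Rmrp (-1.98 ± 0.45, SE), the RNA components of ribonucleases P and MRP. Both lack a poly(A) tail, and in a list of such RNAs, written after these values had been seen, 8 of the 11 other measured members were negative (median -0.73, camera unadjusted p = 0.0148). Counted among these were Rn45s (-1.31 ± 0.44, SE) and Mir6236 (-1.14 ± 0.44, SE), which did not pass in the authors' deposited table. Without them, 6 of 9 were negative (median -0.12, camera unadjusted p = 0.188). Also negative in the authors' deposited table were the kinesin gene Kif13b (-1.86 ± 0.41, SE), the imprinted gene Peg3 (-1.78 ± 0.39, SE) and the GABA receptor subunit gene Gabra2 (-1.57 ± 0.35, SE). There were 229 called genes of 15043 tested in the authors' deposited table, 148 positive and 81 negative. Centring the fold changes on their median of 0.04 gave 100 positive and 96 negative genes, and removing the trend with transcript length and GC content gave 47 positive and 15 negative.

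Oxidative phosphorylation genes were positive in 24 of 26 members in the HCD-weaned females (median 0.52, camera adjusted p = 6.82e-12). The 5 called members in the authors' deposited table were Cox5a (1.28 ± 0.23, SE), Ndufb3 (0.91 ± 0.22), Ndufa2 (1.09 ± 0.29), Sdhb (0.79 ± 0.22) and Ndufa1 (0.79 ± 0.22). Sdhb and Ndufa1 were named after their values were seen, and 14 members passed adjusted over the list alone. Cytosolic ribosomal protein genes had a median of 0.24 (camera adjusted p = 2.73e-05), with 3 members called, Rps29 (1.30 ± 0.21, SE), Rplp2 (1.19 ± 0.27) and Rps28 (0.83 ± 0.25) in the authors' deposited table, and 6 adjusted over the list alone. Of 13 glucocorticoid-responsive genes, 8 were positive (median 0.44, camera adjusted p = 0.0222), with 2 called over all genes and 5 adjusted over the list alone. The 2 were Tsc22d3, which encodes the protein GILZ (1.03 ± 0.18, SE; adjusted p = 1.69e-05), and the kinase gene Sgk1 (1.12 ± 0.22, SE; adjusted p = 0.000337) in the authors' deposited table. The call of this list was lost by ranks (adjusted p = 0.255) and on fold changes (adjusted p = 0.0948). Immediate early genes, which follow neuronal activity, were negative in 14 of 17 members (median -0.31, camera adjusted p = 0.0222), with 0 called over all genes and 1 adjusted over the list alone. Arc stood at -0.76 ± 0.25 (SE; adjusted p = 0.0792) in the authors' deposited table. Heat shock proteins (median 0.36, camera adjusted p = 0.0222), the unfolded protein response (median 0.23, 0.0324) and chromatin enzymes (median -0.22, 0.0222) also passed. Called over all genes and adjusted over the list alone, these held 0 and 0, 1 and 1, and 1 and 4 members. The call of the unfolded protein response was lost on fold changes (adjusted p = 0.0949). Only oxidative phosphorylation and ribosomal proteins of these 7 lists kept their call with a preset correlation of 0.05, the other 5 lists having adjusted p between 0.126 and 0.167. At 0.10 ribosomal proteins did not pass either (adjusted p = 0.144). The Wald statistic fell with transcript length here too (Spearman rho = -0.439, across genes). With the length and GC trend removed ribosomal proteins (adjusted p = 0.112), chromatin enzymes (0.392), heat shock proteins (0.0625) and the unfolded protein response (0.148) did not pass. Pomc (0.23 ± 0.45, SE), Agrp (0.22 ± 0.26), Npy (0.99 ± 0.37; adjusted p = 0.164) and Cartpt (0.22 ± 0.45) did not pass in the authors' deposited table, and the table lists no adjusted p for Agrp.

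**Figure D1:**
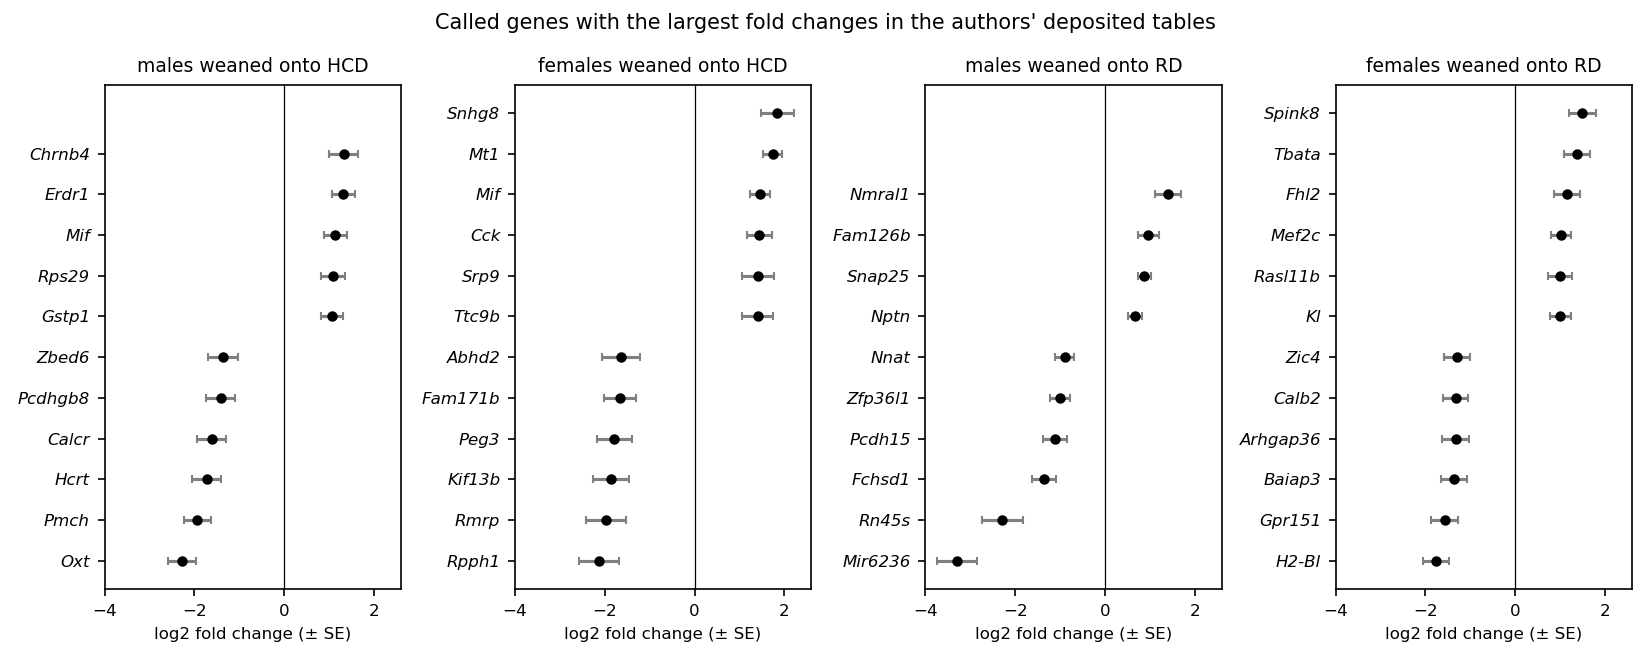
Log2 fold changes (x axis) of up to 6 called genes with the largest positive and up to 6 with the largest negative values under the naming rule in each of the authors' 4 deposited comparisons, with the authors' standard errors as bars and 0 as a vertical line. In the authors' deposited tables Oxt (-2.27), Pmch (-1.93) and Hcrt (-1.73) lie at the negative end in males weaned onto HCD, and Mt1 (1.74) lies near the positive end in females weaned onto HCD.

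In males weaned onto RD, Mir6236 and the ribosomal RNA precursor had the most negative called values and synaptic genes were positive. Mir6236, annotated as a microRNA gene on chromosome 9 from 110281287 to 110281409, had a log2 fold change of -3.28 ± 0.45 (SE; adjusted p = 2.28e-09) in the authors' deposited table, and Rn45s, the ribosomal RNA precursor, -2.29 ± 0.45 (SE; adjusted p = 0.00201). Snap25, which encodes a membrane fusion protein of synaptic vesicle release, stood at 0.88 ± 0.14 (SE; adjusted p = 2.31e-06), a 1.84-fold difference, in the authors' deposited table and lies on chromosome 2 from 136713453 to 136782428. The imprinted gene Nnat, which encodes neuronatin, stood at -0.90 ± 0.22 (SE; adjusted p = 0.0495) and the RNA-binding protein gene Zfp36l1 at -1.01 ± 0.22 (SE; adjusted p = 0.0133) in the authors' deposited table. Of 12920 genes tested, 11 passed in the authors' deposited table, 5 positive and 6 negative, and 555 had an unadjusted p under 0.05, or 4.30%. Dividing the Wald statistic by its robust spread of 0.847 gave 74 called genes, 42 positive and 32 negative.

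Of the gene lists, synapse and fast transmission was positive in 18 of 23 members in the RD-weaned males (median 0.22, camera adjusted p = 0.000288), with Snap25 the 1 called member and the 1 adjusted over the list alone. Syt1, the calcium sensor gene of release, stood at 0.71 ± 0.37 (SE; adjusted p = 1.00) in the authors' deposited table. Cytosolic ribosomal protein genes were negative in 33 of 35 members (median -0.42, camera adjusted p = 2.15e-05), with 0 members called over all genes or adjusted over the list alone. All 8 thalamus markers were positive (median 0.45, camera adjusted p = 0.000757), with 0 called over all genes and 1 adjusted over the list alone. Of 10 markers of ependymal cells and tanycytes, 9 were negative (median -0.33, camera adjusted p = 0.0132), with 0 called either way. The thalamus marker Prkcd stood at 1.41 ± 0.43 (SE; adjusted p = 0.223) in the authors' deposited table. With a preset correlation of 0.05 the ependymal and tanycyte list no longer passed (adjusted p = 0.0502), and at 0.10 none of these 4 lists did (adjusted p between 0.0506 and 0.134). In the authors' deposited table Pomc stood at -0.10 ± 0.38 (SE), Npy at 0.17 ± 0.45 and Cartpt at -1.05 ± 0.42 (adjusted p = 0.762), and Agrp, at 0.21 ± 0.28, had no adjusted p. Neither Oxt nor Pmch has a p-value in this deposited table of the authors.

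In females weaned onto RD, markers of cortex, hippocampus and striatum were positive, and thalamus markers and transcription factors of hypothalamic neurons were negative. Spink8, a protease inhibitor gene (1.50 ± 0.30, SE; adjusted p = 0.00113), and the transcription factor gene Mef2c (1.02 ± 0.23, SE; adjusted p = 0.00848) were positive in the authors' deposited table, as was Kl, the klotho gene expressed in choroid plexus (1.01 ± 0.23, SE; adjusted p = 0.00867). The orphan receptor gene Gpr151 (-1.57 ± 0.29, SE; adjusted p = 0.00035), the calretinin gene Calb2 (-1.32 ± 0.28, SE; adjusted p = 0.00473), the transcription factor gene Zic4 (-1.30 ± 0.29, SE; adjusted p = 0.00626) and Itih3 (-1.28 ± 0.22, SE; adjusted p = 3.40e-05) were negative in the authors' deposited table. Itih3 lies on chromosome 14 from 30908572 to 30923760 and Gpr151 on chromosome 18 from 42577881 to 42579652. Named after their values were seen, the angiotensinogen gene Agt (-0.79 ± 0.21, SE; adjusted p = 0.046) and the imprinted genes Nnat (-1.19 ± 0.24, SE; adjusted p = 0.00113) and Dlk1 (-1.12 ± 0.30, SE; adjusted p = 0.0479) were also negative in the authors' deposited table. Of 15028 genes tested, 52 passed in the authors' deposited table, 18 positive and 34 negative. H2-Bl had the largest negative value among the called genes in the authors' deposited table (-1.77 ± 0.29, SE). It belongs to the class I histocompatibility genes and is annotated in GENCODE M21 as a polymorphic pseudogene. Its paralogs are close, so reads could have been divided among them.

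Cortex and hippocampus markers had a median of 0.79 in the RD-weaned females, with 7 of 8 positive (camera adjusted p = 8.50e-08), 0 called over all genes and 5 adjusted over the list alone. Emx1 (1.06 ± 0.30, SE; adjusted p = 0.0756) and Tbr1 (1.00 ± 0.29, SE; adjusted p = 0.092), transcription factor genes of cortical neurons, did not pass singly in the authors' deposited table. All 10 striatum markers were positive (median 0.40, camera adjusted p = 0.00164), as were 9 of 11 choroid plexus markers (median 0.49, camera adjusted p = 6.90e-07). Of the choroid plexus markers, 1 was called over all genes, Kl, and 3 adjusted over the list alone. Markers of microglia and macrophages were positive in 13 of 17 members (median 0.27, camera adjusted p = 0.00197) and those of mature oligodendrocytes in 11 of 13 (median 0.23, camera adjusted p = 0.0129). Immediate early genes were positive in 12 of 15 members (median 0.30, camera adjusted p = 0.000516), with 2 adjusted over the list alone. All 9 hypothalamic transcription factors were negative (median -0.33, camera adjusted p = 1.40e-05), with 0 called over all genes and 2 adjusted over the list alone. Thalamus markers were negative in 6 of 7 members (median -0.26, camera adjusted p = 0.0191), 1 of them passing adjusted over the list alone, and chromatin enzymes had a median of -0.10 (camera adjusted p = 0.00945). Apart from Kl, 0 members of these lists were called over all genes, and striatum, microglia, oligodendrocyte and chromatin lists held 0 adjusted over the list alone. With a preset correlation of 0.05, chromatin enzymes (adjusted p = 0.102), oligodendrocytes (0.0543) and thalamus (0.0543) no longer passed, and microglia did not at 0.10 (0.091). Oligodendrocytes did not pass on fold changes (adjusted p = 0.0652), nor chromatin enzymes with the length and GC trend removed (adjusted p = 0.132). Pomc (0.36 ± 0.23, SE) had no p-value, and Agrp (-0.05 ± 0.22), Npy (0.89 ± 0.28; adjusted p = 0.167) and Cartpt (-0.48 ± 0.24; adjusted p = 0.793) did not pass in the authors' deposited table.

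**Figure D2:**
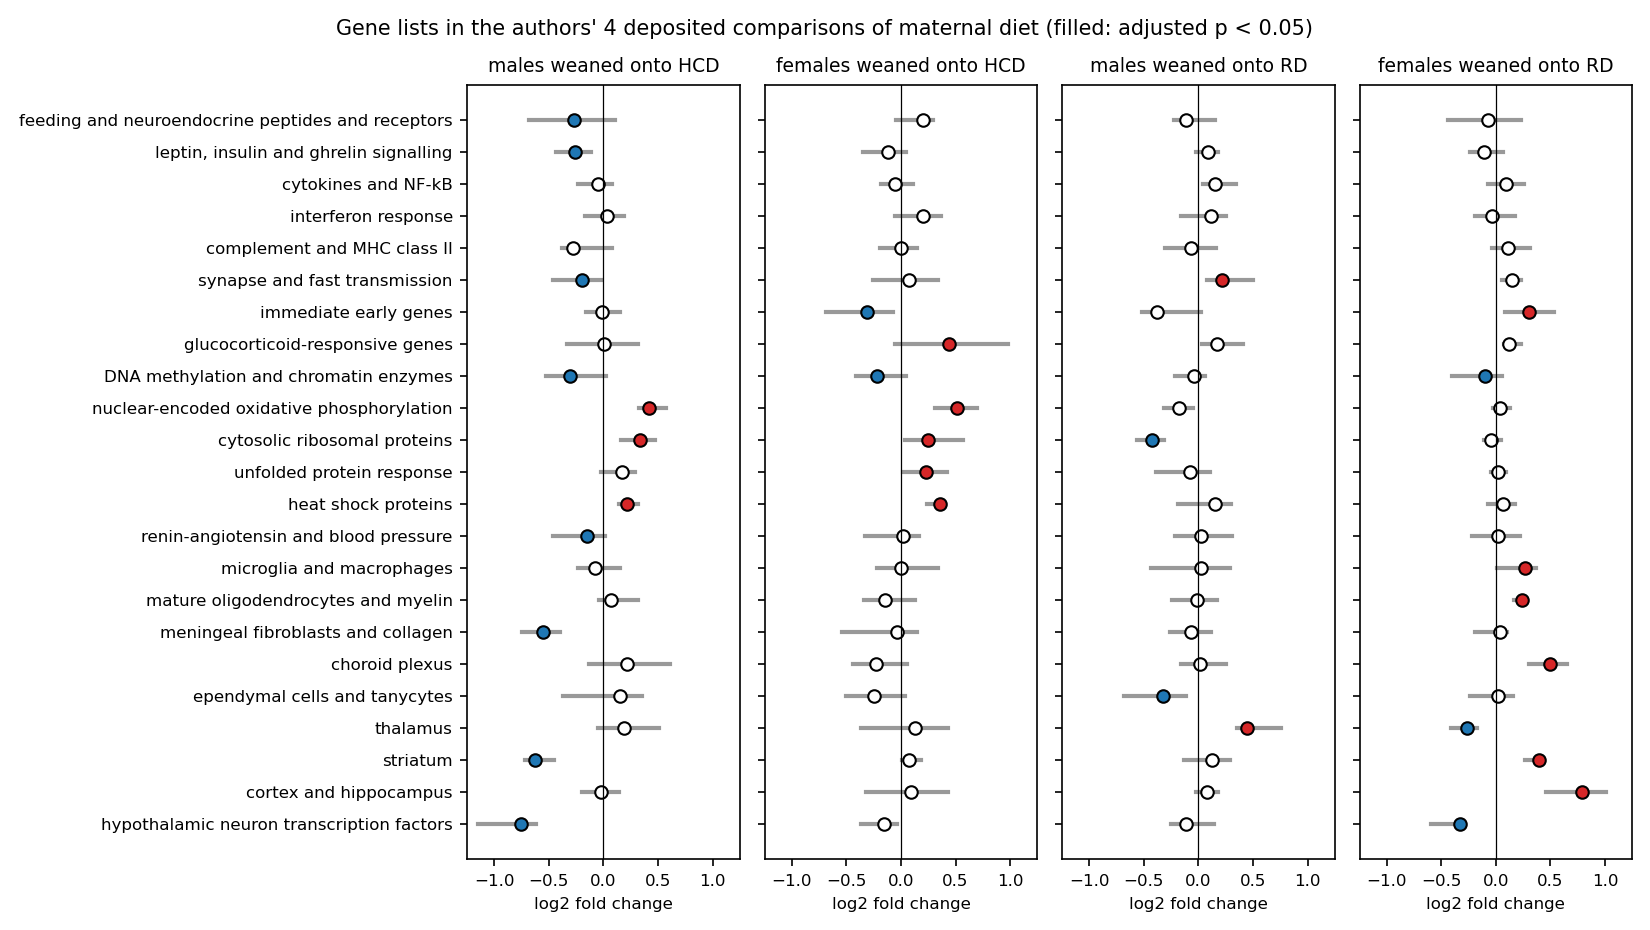
Median log2 fold change (x axis) of the members of 23 gene lists (y axis) in each of the authors' 4 deposited comparisons, with grey lines from the lower to the upper quartile of the members. Filled points passed the camera test, red for positive and blue for negative medians: hypothalamic neuron transcription factors pass at -0.76 in males weaned onto HCD and -0.33 in females weaned onto RD, and oxidative phosphorylation passes at 0.42 and 0.52 in the HCD-weaned males and females.

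The series asks about hypothalamic inflammation, and the inflammatory lists did not pass in either HCD-weaned comparison. Cytokine and NF-kB genes had medians of -0.05 in HCD-weaned males, -0.05 in HCD-weaned females, 0.15 in RD-weaned males and 0.09 in RD-weaned females (camera adjusted p between 0.373 and 0.705). Interferon response genes ranged in median from -0.04 to 0.21 (camera adjusted p between 0.251 and 0.921), and complement and MHC class II genes from -0.28 to 0.11 (camera adjusted p between 0.149 and 0.944). With the length and GC trend removed, complement and MHC class II genes passed with a negative direction in HCD-weaned males (adjusted p = 0.000818). Without a filter on low counts, cytokine and NF-kB genes passed with a positive direction in RD-weaned males (adjusted p = 0.0372). Microglia and macrophage markers passed in RD-weaned females and had camera adjusted p between 0.670 and 0.883 in the other 3 comparisons. The difference of the inflammatory lists between sexes was not past the threshold on either postnatal diet (camera adjusted p between 0.142 and 0.689).

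The maternal comparisons shared few called genes. HCD-weaned males and females shared 5 of the genes called among 14947 tested in both, against 0.29 by chance (Fisher's exact test, one-sided, adjusted p = 4.63e-05 over 6 pairs), namely Erdr1, Gstp1, Malat1, Mif and Rps29, all with the same sign. The chance value treats genes as exchangeable, whereas the Wald statistic fell with transcript length in both of these comparisons. No overlap was recomputed with that trend removed, so the trend can account for part of the sharing. HCD-weaned males and RD-weaned females shared Calcr, Irs4 and Myh6 (adjusted p = 0.000134). As read, each had the same sign in both, and all 3 would have opposite signs if the sign of the RD-weaned table were turned. RD-weaned males and females shared Nnat (adjusted p = 0.0646). The log2 fold changes of HCD-weaned males and females correlated across genes with a Pearson r of 0.64 and a Spearman rho of 0.65, although genes are not independent. Of 228 genes called in the females and tested in both, 228 had the same sign in the males. Of 19 called in the males, 17 had the same sign in the females. These counts of signs were not repeated with the length and GC trend removed. For the other 5 pairs, each with a table of RD-weaned offspring, Pearson r lay between 0.02 and 0.32 as read, and turning 1 table of a pair turns its sign. The 4 comparisons share no samples in the labels.

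As the tables were read, tests of the difference between 2 comparisons found few single genes. Between males and females weaned onto HCD, 0 of 14947 genes passed (normal test of the difference of the authors' deposited fold changes), with 96 at an unadjusted p under 0.05, or 0.642%. So low a share points to a conservative test, and the lack of called genes does not show equal effects. With the statistic divided by its robust spread 3 genes passed. Gpr151 differed between RD-weaned males (1.00 ± 0.40, SE) and females (-1.57 ± 0.29, SE) by 2.57 ± 0.50 (SE; adjusted p = 0.00295), from the authors' deposited tables. Thalamus markers differed in the same direction there (median difference 0.94, camera adjusted p = 3.91e-06), so a difference in the dissected tissue stays open for this gene. Mir6236 differed between HCD-weaned males (-0.46 ± 0.32, SE) and RD-weaned males (-3.28 ± 0.45, SE) by 2.82 ± 0.55 (SE; adjusted p = 0.00379), and Mt1 between HCD-weaned females (1.74 ± 0.21, SE) and RD-weaned females (0.04 ± 0.25, SE) by 1.69 ± 0.33 (SE; adjusted p = 0.00446), from the authors' deposited tables. With the sign of the RD-weaned table that is subtracted turned, Gpr151 would differ by -0.57 (adjusted p = 0.999), Mir6236 by -3.74 (adjusted p = 1.29e-07) and Mt1 by 1.78 (adjusted p = 0.000173). The number of genes that differ would then be 14 between sexes on RD, 4 between diets in males and 186 between diets in females. With the length and GC trend removed and the signs as read, 0 genes passed for either difference between postnatal diets. As groups, feeding peptides and receptors were more negative in HCD-weaned males than females by a median of -0.44 (camera adjusted p = 1.44e-07), and hypothalamic transcription factors by -0.76 (camera adjusted p = 0.00297, and 0.0697 by ranks). Oxt (-0.99 ± 0.45, SE), Pmch (-0.59 ± 0.42) and Hcrt (-0.43 ± 0.45) were also negative in HCD-weaned females, but did not pass in the authors' deposited table. Markers of other tissues differed between HCD-weaned males and females as well. The median difference was -0.85 for striatum (camera adjusted p = 7.08e-08), -0.50 for meningeal fibroblasts (camera adjusted p = 8.00e-05) and 0.53 for choroid plexus (camera adjusted p = 0.00028).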

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

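The comparisons of effects between sexes and postnatal diets were planned. The tests that weigh the 3 patterns were added after the called genes, the medians of the lists and the correlations between tables had been seen, and the tests of tissue markers in HCD-weaned males, that of thalamus markers in RD-weaned females and the turning of signs were chosen only after their own result or the values behind it were seen.

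Effects that differed between groups by a test of the difference itself are given first. Unequal shrinkage of the fold changes, which was not tested, could contribute to any of these differences. Single genes were Gpr151, which differed between RD-weaned males and females by 2.57, Mir6236, which differed between HCD-weaned and RD-weaned males by 2.82, and Mt1, which differed between HCD-weaned and RD-weaned females by 1.69, all in log2 units from the authors' deposited tables. Between sexes on HCD, the median difference (male minus female) was -0.44 for feeding peptides and receptors, -0.27 for synapse, -0.33 for glucocorticoid-responsive genes, -0.23 for the circadian clock, -0.50 for meningeal fibroblasts, -0.85 for striatum and -0.76 for hypothalamic transcription factors. It was 0.18 for immediate early genes, 0.18 for astrocytes, 0.21 for mature oligodendrocytes, 0.53 for choroid plexus and 0.37 for ependymal cells.

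The other differences subtract a table of RD-weaned offspring, whose sign rests on the order of the groups alone, so the median with that sign turned follows in brackets. Only lists that passed as read are given. These number 5 between sexes on RD, 9 between diets in males and 7 between diets in females. With the sign turned, 7, 6 and 8 lists passed in the same order, some of them only then. Between sexes on RD (male minus female), the median difference was -0.55 for immediate early genes (turned 0.05), -0.38 for ribosomal proteins (turned -0.47), -0.29 for ependymal cells (turned -0.48), 0.94 for thalamus (turned 0.35) and -0.81 for cortex and hippocampus (turned 1.01). Here only the female table is turned, and turning both would turn each sign. Between postnatal diets in males (HCD minus RD), it was -0.38 for leptin, insulin and ghrelin signalling (turned -0.19), -0.67 for synapse (turned 0.02), -0.33 for the circadian clock (turned 0.04), -0.37 for meningeal fibroblasts (turned -0.72) and -0.77 for striatum (turned -0.67). In the same comparison it was 0.62 for oxidative phosphorylation (turned 0.22), 0.79 for ribosomal proteins (turned -0.14), 0.37 for the unfolded protein response (turned 0.14) and 0.50 for ependymal cells (turned -0.23). Between postnatal diets in females (HCD minus RD), it was -0.67 for immediate early genes (turned 0.04), -0.37 for mature oligodendrocytes (turned 0.11), -0.60 for choroid plexus (turned 0.13) and -0.54 for cortex and hippocampus (turned 0.75). It was 0.47 for oxidative phosphorylation (turned 0.63), 0.31 for ribosomal proteins (turned 0.28) and 0.63 for thalamus (turned -0.16). The lists that passed with the same direction under both signs were ribosomal proteins between sexes on RD, oxidative phosphorylation, meningeal fibroblasts and striatum between diets in males, and oxidative phosphorylation and ribosomal proteins between diets in females. Gpr151 would differ by -0.57, Mir6236 by -3.74 and Mt1 by 1.78 with the sign turned. Of all list differences as read, those that hold with a preset correlation of 0.10 number 8 between sexes on HCD, 1 between sexes on RD, 4 between diets in males and 6 between diets in females.

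A first pattern is that HCD-weaned males and females share positive oxidative phosphorylation genes and correlated fold changes. Transcript length and GC content, which can stand for RNA quality or library size selection, accounted for part of both tables. By the tests that follow they left a part unaccounted for, though these tests cannot exclude a remainder of the same bias. The median Wald statistic of oxidative phosphorylation genes was 2.27 in females, above the upper end of 2.10 of the central 95% of random lists matched on mean, length and GC, and 1.51 in males, above 1.31, although the matched lists themselves had medians of 1.52 and 1.02. Random lists were drawn gene by gene, without the correlation within a pathway, so their interval can be too narrow. With the trend removed, the Wald statistics of both sexes still correlated across genes (r = 0.569, from 0.670 before). A remainder of that trend, another shared technical difference and the maternal diet all stay open.

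A second pattern is that tissue markers moved with maternal diet: in RD-weaned females a separate set of telencephalic genes, in none of the marker lists, was positive in 11 of 11 measured members, with a median Wald statistic of 2.44 against 0.899 at the upper end of the central 95% of matched random lists. This is consistent with more telencephalic tissue in the dissections of 1 group, though some of these genes are also expressed in hypothalamus. Thalamus markers moved the other way there, with 6 of 7 negative and a median of -0.26 (-0.43 to -0.17, 95% bootstrap interval). The interval resamples marker genes and carries no spread between animals. For these samples the thalamus values argue against more of all neighbouring forebrain tissue in that group. In HCD-weaned males striatum markers had a median of -0.63 (-0.75 to -0.40, by the same resampling of genes). For these samples this argues against more striatal tissue in offspring of HCD dams. Cortex, hippocampus, striatum and thalamus markers together had a median of -0.22 (-0.46 to 0.06) in these males, so other neighbouring tissue, a different border of the dissection and an effect of maternal diet on these neurons stay open.

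The last pattern is the negative values of Rn45s, the ribosomal RNA precursor, and Mir6236, annotated as a microRNA gene, in RD-weaned males. If RNA without a poly(A) tail had been carried over unequally, other such RNAs would be expected to be negative as well. The 6 other measured RNAs of this kind had a median Wald statistic of -0.837, at the 4.15th percentile of matched random lists, so unequal carry-over cannot be told apart from other explanations with so few members. The measured RNAs of this kind differed in number between comparisons. The 8 in HCD-weaned males had a median of -0.857, within the central 95% of random lists, and the 8 in RD-weaned females -0.999, below it. In HCD-weaned females the median of 9 such RNAs was -0.383, within it, once Rpph1 and Rmrp, seen to be negative there before the list was written, were left out. With them the median of 11 was -1.90. In RD-weaned females Rn45s stood at -0.29 ± 0.19 (SE) and Mir6236 at -0.29 ± 0.20 (SE) in the authors' deposited table. Neither has a p-value there, although their mean normalized counts were 22072.5 and 8902.13. Whether single libraries stand behind the values of these 2 genes could not be tested without mapped libraries. No biological explanation was tested.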

How the results depend on the processing

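The threshold of 0.10 and the removal of the filter were planned, and the other settings were added after the data were seen. No paired analysis was possible because the library columns carry no label that ties them to a sample or replicate number. For the same reason the planned normalizations, other tools, joint fit, estimated correlation and leave-one-out fits were not run, and no other split of the samples was tested. The deposited standard errors limit single genes: in simulation 19% of log2 changes of 1 were recovered in RD-weaned males. The part of depth in this was not tested.

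Counts of called genes moved by more than 1.5 times as follows, and the cause was not tested except where fewer genes were adjusted over or a threshold was relaxed. At an adjusted p under 0.10 they were 450 in HCD-weaned females, 23 in RD-weaned males, 90 in RD-weaned females and 12 for the diet difference in females. Without a filter on low counts the differences gave 3 genes between sexes on RD, 4 between diets in males and 3 between diets in females. Over genes with a mean of 10 or more they gave 2 between sexes on RD and 4 between diets in males. Over genes with a mean of 100 or more the counts were 16 in HCD-weaned males, 2 between sexes on RD and 2 between diets in females. With the Wald statistic divided by its robust spread they were 3 in HCD-weaned males, 56 in HCD-weaned females, 74 in RD-weaned males, 3 between sexes on HCD and 12 between diets in females. With the length and GC trend removed they were 62 in HCD-weaned females, of which 54 were among the 229, and 0 for both diet differences.

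Counts of lists that passed fell with a larger preset correlation. At 0.05 they were 7 in HCD-weaned males, 2 in HCD-weaned females and 4 for the diet difference in males. At 0.10 they were 6, 1, 0 and 5 in HCD-weaned males, HCD-weaned females, RD-weaned males and RD-weaned females, with 1 between sexes on RD and 4 between diets in males. With the length and GC trend removed they were 3 in HCD-weaned females and 3 between sexes on RD, and without a filter 8 in RD-weaned males. The direction turned, with no list passing on either side, with the trend removed for interferon response in HCD-weaned males (adjusted p = 0.554) and, in HCD-weaned females, complement (0.446), feeding peptides (0.303) and microglia (0.856). It also turned for complement in HCD-weaned females by ranks (0.928) and, without a filter, for cytokines in HCD-weaned males (0.933) and microglia in RD-weaned males (0.900). Of the named genes, Pomc (-0.26) and Cartpt (-0.15) in HCD-weaned females and Pomc (0.0078) and Hcrt (0.0282) in RD-weaned males turned with the trend removed, none of them called.

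With the sign of the subtracted RD-weaned table turned, the differences gave 14 genes between sexes on RD, 4 between diets in males and 186 between diets in females, of which 0, 1 and 1 were among those called as read. Of the list differences that passed as read, the direction, as camera gives it, then turned for cortex and hippocampus (adjusted p = 0.000221) and immediate early genes (0.62) between sexes on RD. Choroid plexus, striatum and hypothalamic transcription factors turned as well there and passed only when turned (camera adjusted p = 0.0248 each). Between diets in males the direction turned, among lists that passed as read, for the circadian clock (0.951), ribosomal proteins (0.951), ependymal cells (0.283) and synapse (0.637). Thalamus markers turned there from a median of -0.39 to 0.79 and passed only when turned (camera adjusted p = 0.000593). Between diets in females the direction of lists that passed as read turned for choroid plexus (0.468), cortex and hippocampus (0.0409), oligodendrocytes (0.938) and thalamus (0.625). The median of immediate early genes changed sign (0.04) where the camera direction did not. Hypothalamic transcription factors turned from a median of 0.20 to -0.46 and passed only when turned (camera adjusted p = 0.0266). The differences of Gpr151 (-0.57) and Mir6236 (-3.74) turned as well.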

Other observations

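The list and the test of imprinted genes were chosen after called genes had been seen.

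Imprinted genes, which are expressed from 1 parental copy and of which several act in hypothalamic growth and feeding circuits, appeared among the called genes of every comparison, with negative values as the tables were read. They were Peg10 in HCD-weaned males, Peg3 and Meg3 in HCD-weaned females, Nnat in RD-weaned males, and Nnat and Dlk1 in RD-weaned females, and no imprinted gene of the list was called with a positive value in the authors' deposited tables. If the sign of the RD-weaned tables were turned, Nnat and Dlk1 would be positive there, opposite to Peg10, Peg3 and Meg3. Nnat, on chromosome 2 from 157560078 to 157562522, stood at -0.12 ± 0.26 (SE) in HCD-weaned males and -0.66 ± 0.23 (SE; adjusted p = 0.109) in HCD-weaned females in the authors' deposited tables.

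A hypothesis is that maternal diet may act on imprinted genes as a class. With called genes left out, the remaining imprinted genes passed with a negative direction in 2 of 4 comparisons by the camera statistic of limma, adjusted over the 4. These were HCD-weaned males (adjusted p = 0.00014, 24 of 33 genes negative, median -0.28) and RD-weaned females (adjusted p = 3.17e-07, 25 of 31 negative, median -0.29). With the sign of the RD-weaned female table turned, the list would be positive there and negative in 1 of 4 comparisons. The remaining genes did not pass in HCD-weaned females (adjusted p = 0.122) or RD-weaned males (adjusted p = 0.928). The 2 comparisons that passed are also those in which the list of hypothalamic transcription factors passed with a negative direction, and both signs would turn together, so a change in the share of hypothalamic neurons stays open beside an effect on imprinted genes. The imprinted list was not tested with the length and GC trend removed, so that trend stays open too. Spearman rho of the Wald statistic with transcript length was -0.545 in HCD-weaned males and -0.22 in RD-weaned females.

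The deposited tables of RD-weaned offspring list no p-value for 1653 genes with a mean above 0 in males and 462 in females, and those of HCD-weaned offspring for 0 genes. Oxt and Pmch are among those in males, and Pomc, Rn45s and Mir6236 among those in females. The reason for the missing p-values was not tested.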
